A study of Drosophila melanogaster with 2 samples.

How the data were processed

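Chromatin was immunoprecipitated with an anti-GFP antibody from whole embryos (0 to 18 h) that express a Doc2-eGFP fusion protein, and was fragmented by sonication to 200 to 800 bp, per the labels. There was 1 group with 2 biological replicates, numbered as in the labels. Each replicate had an IDR thresholded and an IDR ranked peak list of its own, and the series had a thresholded list, a conservative thresholded list and 2 ranked lists, all on dm6 and made against a control, per the deposited notes on the files. The aligner, the peak caller and their settings are not given in the sources used here, and the control library was not analysed here.

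The signal of each peak is the value the authors' peak caller gave it, used as deposited to describe, rank or filter peaks within a list. The score is the scaled IDR score the authors deposited, with a lowest value of 830 in every thresholded list, an IDR of 0.01. The ranked lists also give the deposited −log10 of the IDR, and for 99.997% of 542666 ranked peaks the score followed from it within 1. The series thresholded list is contained in the ranked list whose compared columns are not the replicates' own peaks, so it was taken as made from pooled reads. The conservative list is contained in the ranked list whose first compared column matched peaks in the own list of replicate 1 for 82.4% of peaks and whose second matched the own list of replicate 2 for 81.5%, so it was taken as a comparison of the replicates. Because the match rests on values, those columns were used only as the first and second replicate compared. Read counts were not used here, so depth is unknown and no counting interval is given for a signal.

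Peaks on X, 2L, 2R, 3L, 3R and 4 were analysed, which left out 90 of 1230 series peaks on Y and unplaced sequence. Merging overlapping peaks on these chromosomes would remove 41, among them weak second peaks beside strong ones, and they were kept in the counts. Positions are 1-based. Gene models were those of Ensembl release 115 for the same assembly, with 13945 protein-coding genes. Dl of the Notch list was not matched to a single current symbol and was left out, and h was matched to hry. A summit in several annotation classes was counted as 5' UTR, coding exon, 3' UTR, intron and intergenic, in that order of priority.

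Overlap of the replicates was compared with 1000 random placements of the smaller list on the same chromosomes. Promoter share (summit within 500 bp of a protein-coding TSS) was compared with 1000 placements on the same arm, and annotation classes with 200. Motif and 6-mer presence within 100 bp of summits, on either strand, was compared with windows 1000 bp to the left and right of the same summits by two-sided Fisher's exact tests with Benjamini-Hochberg adjustment over 15 motifs or 2080 6-mers. For lists of genes, each peak went to the gene with the nearest TSS, and the number of members with a peak was compared with 10000 random lists of the same size, matched on deciles of the length of genome nearest to a gene, drawn from the 11310 genes with a ranked peak. List members without a ranked peak were left out of that test. All members found in the gene models were counted in the unmatched Fisher's exact test, with gene bodies and 5 kb, and against draws of ranked peaks. The p-values for genome positions treat peaks as the units and say nothing of the spread between embryos beyond these 2 replicates. The genes named are the nearest genes of the 20 series peaks of highest signal that overlap a thresholded peak of both replicates, the members of both T-box lists, and up to 4 members with a peak of highest signal from each other list. The tests, lists, alternatives and this rule were set before the data were examined, except where the text says otherwise. The alternatives were other peak lists, each replicate alone, other windows, distances, backgrounds and ways to give peaks to genes.

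The tests were tried on simulated data. With peaks at random positions, no 6-mer of 2080 passed in 5 runs, no gene list of 18 in 20 runs, and the promoter test in none of 5 runs. The T-box site planted in 10% of 1140 windows was found in 5 of 5 runs, a list with 60% of its members given a peak in 20 of 20 runs, and a promoter share of 40% in 5 of 5 runs. Random positions lack the base composition and promoter share of the real peaks, so these runs do not show how the tests behave on such peaks. The planted T-box site was called before adjustment over motifs, and weaker plants were not tried. Analyses were run in Python 3.11.15 with numpy 2.4.6, pandas 2.3.3, scipy 1.17.1 and matplotlib 3.10.9.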

Results

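Doc2 is 1 of the 3 Dorsocross proteins of Drosophila melanogaster, T-box transcription factors known from amnioserosa, dorsal ectoderm and heart development. Its chromosomal binding was measured by chromatin immunoprecipitation and sequencing (ChIP-seq) with an anti-GFP antibody in whole embryos, collected from 0 to 18 h, of a transgenic line that expresses a Doc2-eGFP fusion protein. The data set held 1 group of 2 biological replicates, so the comparisons were between the replicates and between peaks and the rest of the genome. Peaks were called by the authors and filtered by irreproducible discovery rate (IDR), a measure of how well peak ranks repeat between the sets of peaks compared. Those sets were the replicates only for the conservative list. The series list held 1230 peaks on dm6, of which 1140 lay on chromosomes X, 2L, 2R, 3L, 3R and 4, and a conservative list, built by comparing the replicates with each other, held 1143. The own list of replicate 1 held 821 peaks and that of replicate 2 held 515. Read depth is unknown from these files. The peak signal values are the authors' and their scale is not given in the sources used here.

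The first question was whether the replicates recovered the same regions. The 20 shared peaks of highest signal lay nearest to CG11050, CG14100, Ugalt, mRpL41, CG7601, Tcs5, CG5611, ph-p, CenG1A, eIF6, HmgZ, Chro, Adf1, PNPase, Art3, CG32772, CG4004, Trl, GstE13 and mRpL23. Of the 468 peaks of replicate 2 on these chromosomes, 393 (84.0%) overlapped a peak of replicate 1 by at least 1 bp, against a mean of 1.62 and a maximum of 7 in 1000 random placements (one-sided permutation p = 0.001, the smallest these placements can give). In the other direction, 388 of 777 peaks of replicate 1 (49.9%) overlapped a peak of replicate 2. Among the 285 series peaks with the highest signal, 95.4% overlapped a peak in the lists of both replicates, and among the 285 with the lowest, 2.46% did. In all, 365 of the 1140 series peaks (32.0%) met a peak in the list of neither replicate.

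Across the 1143 conservative peaks, the signal in the 2 replicates had a Spearman rho of 0.682 (95% bootstrap interval 0.643 to 0.718), a value across peaks, which are not independent replicates. The signal was higher in the first replicate compared at 864 peaks (75.6%), with a median ratio of 1.22. These peaks had been selected for repeatable ranks, and across all 144725 peaks of the ranked list before that selection rho was 0.260. Pearson's r of the log2 signal over the conservative peaks was 0.842.

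**Figure D1:**
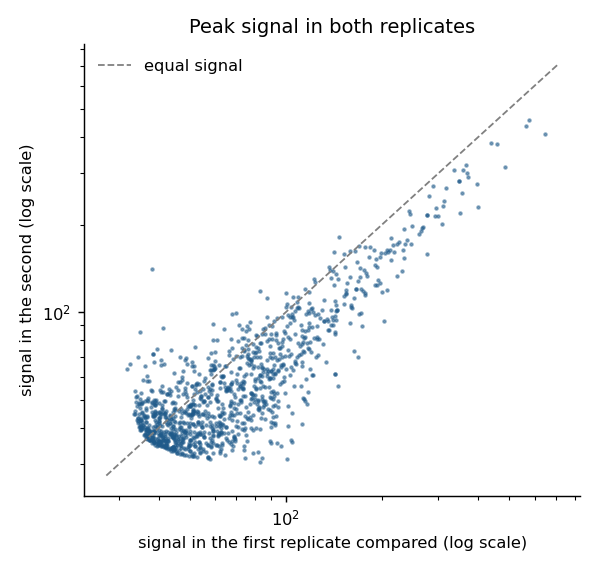
Each point is 1 of the 1143 conservative peaks, with its signal in the first replicate compared on the x axis and in the second on the y axis, both on log scales, and the dashed line marks equal signal. Of these points, 864 lie below the line, and rho is 0.682.

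The second question was where in the genome the peaks lay. They concentrated just upstream of transcription start sites (TSSs) of protein-coding genes. The peak of highest signal lay in an intron of CG11050 (FBgn0031836; 2L, 6612562 to 6612864), 1025 bp downstream of the nearest TSS, with a signal of 1054 in the series list, 578 in replicate 1 and 456 in replicate 2. The next lay in intergenic sequence 108 bp upstream of CG14100 (FBgn0036889; 3L, 19590483 to 19590756), with a signal of 1038, and the one after that 29 bp upstream of Ugalt, a UDP-galactose transporter (FBgn0024994; X, 2703742 to 2704028), with 1001. Of the 20 shared peaks of highest signal, 13 had a summit within 500 bp of a TSS and 9 of those were upstream of it. They included sites 119 bp upstream of the mitochondrial ribosomal protein gene mRpL41, 108 bp upstream of Tcs5, a gene of tRNA modification, and 127 bp upstream of the arginine methyltransferase gene Art3, all intergenic. The site 102 bp upstream of eIF6, a ribosome assembly factor, lay in an intron of the neighbouring gene ytr. Sites in 5' UTRs were those of Chro, which encodes the chromosomal protein Chromator, PNPase, GstE13 and mRpL23. Others lay in introns of genes of chromatin and transcription: ph-p, a Polycomb group gene (X, 2137231 to 2137483, 501 bp upstream of the nearest TSS of the gene), Adf1 and Trl, which encodes the GAGA factor. None of the 20 genes belonged to a gene list fixed in advance, a count of 0 for developmental and housekeeping lists alike. The lists hold only a small share of the 13945 protein-coding genes, so this count says little either way.

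Of all 1140 summits, 503 (44.1%) lay within 500 bp of a protein-coding TSS, against 11.5% ± 0.940 (SD over 1000 random placements on the same chromosome arms; two-sided permutation p = 0.002, the smallest these placements can give). The share was also compared with that of the 138925 ranked peaks that did not reach the IDR threshold and overlapped no series peak. Of these, 9.55% were at a TSS, a difference past the threshold (Fisher's exact p = 1.1e-200). Of the 503 promoter summits, 429 (85.3%) were upstream of the nearest TSS, with a median position of -122 bp. The promoter share fell with signal rank, from 64.9% of the 285 peaks with the highest signal to 51.6%, 36.8% and 23.2% in the following sets of 285. Summits were found in intergenic sequence (479, 42.0%, against 32.9% of random positions), introns (522, 45.8%, against 41.9%) and 5' UTRs (70, 6.14%, against 3.37%) more often than random positions, and in coding exons (59, 5.18%, against 16.9%) and 3' UTRs (10, 0.877%, against 4.97%) less often, each with a two-sided permutation p of 0.01 after Benjamini-Hochberg adjustment, the smallest that 200 placements can give.

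**Figure D2:**
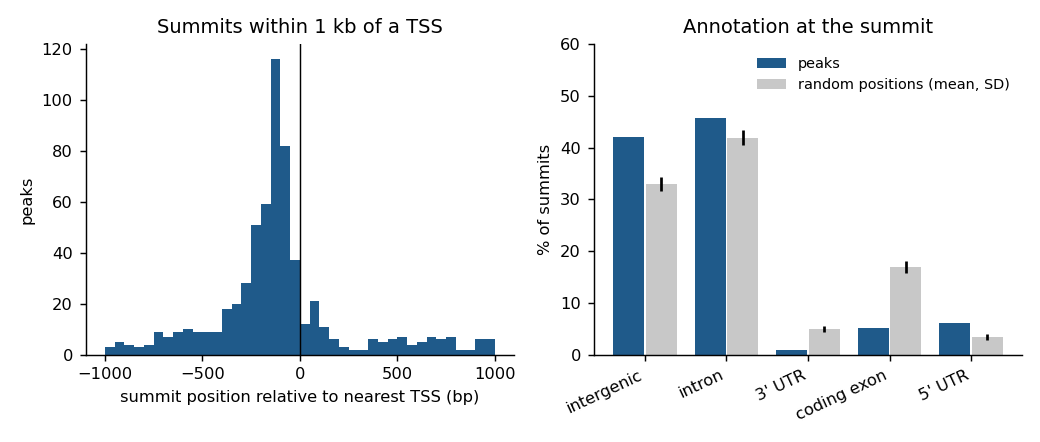
Left, histogram of summit positions relative to the nearest TSS in bp (negative values upstream) for summits within 1 kb, in counts of peaks. Right, percent of the 1140 summits in each annotation class beside the mean and SD of random positions: 5.18% of summits and 16.9% of random positions were in coding exons.

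The X chromosome held 202 of the 1140 peaks (17.7%) and 17.5% of the ranked peaks, a difference not past the threshold (two-sided Fisher's exact p = 0.814). Among the 570 peaks with the highest signal the share on X was 20.7% (Fisher's exact p = 0.0466, not adjusted over the settings tried). It was not past the threshold with the conservative list or with the list of either replicate alone (Fisher's exact p from 0.0520 to 0.685). Chromosome 4 had no peak in the series list, where 0.480 would be expected from its share of ranked peaks. That share was itself low, with 59 ranked peaks over 1348131 bp, against 24493 over the 23542271 bp of X. An expectation from the length of chromosome 4 would be higher. The ranked list had 2 peaks there that reached the IDR threshold and were left out of the series list, and the conservative list held 1 peak there.

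The third question was which sequences lay under the summits, first the binding site of the tagged factor's own family. The T-box site GGTGTGA was found within 100 bp of 18 of 1140 summits (1.58%) and in 45 of 2280 windows of the same width 1000 bp to either side (1.97%), an odds ratio of 0.810 (95% interval 0.469 to 1.40; Fisher's exact adjusted p = 0.735 over 15 motifs). Against ranked peaks below the threshold matched on GC content, the background share was 0.921% and the odds ratio 1.73 (0.926 to 3.24; Fisher's exact adjusted p = 0.194). The interval against flanking windows ends at 1.40, and the one against matched peaks at 3.24. Summits were poorer in GC than the sequence around them, as given below, which can lower the count of this G-rich site. The comparison with flanks therefore does not exclude an enrichment.

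In the panel of 15 motifs, 3 were more frequent at summits than beside them and 2 less frequent. The DNA replication-related element TATCGATA, a promoter element known from housekeeping genes, was in 2.02% of summit windows and 0.526% of flanks (Fisher's exact adjusted p = 0.000473). The Mef2 site YTAWWWWTAR was in 11.1% against 5.75% (Fisher's exact adjusted p = 4.8e-07) and the forkhead site RTAAAYA, used by Biniou, in 33.6% against 23.5% (Fisher's exact adjusted p = 8.9e-09). The Scalloped site GGAATG was in 6.49% against 9.65% (Fisher's exact adjusted p = 0.00557), and the Mad site GCCGNCG in 5.88% against 9.04% (Fisher's exact adjusted p = 0.00479). No difference past the threshold was found for the GATA, Tinman, Zelda, GAGA factor, Twist, Pangolin, Grainy head, homeodomain and Su(H) sites. Of these, the homeodomain site TAATTA, at 14.4% against 11.8% (Fisher's exact adjusted p = 0.0821), was past the threshold with the conservative list, with the list of either replicate alone, with the 570 peaks of highest signal and in windows of 50 bp to either side (Fisher's exact adjusted p from 0.000431 to 0.0105). It was at 14.4% against 15.4% with background peaks matched on GC content (Fisher's exact adjusted p = 0.675). The GAGA factor site was less frequent at summits than beside them within 50 bp (0.702% against 1.93%, Fisher's exact adjusted p = 0.0138) and more frequent within 250 bp (15.3% against 8.20%, Fisher's exact adjusted p = 9.5e-09), where the GATA site was less frequent (19.4% against 23.0%, Fisher's exact adjusted p = 0.0392). GC content was 36.5% in the 50 bp to the right of summits and 37.4% in the 50 bp to the left, and between 42.7% and 44.7% from 100 to 600 bp. With background peaks matched on GC content, the Mef2, forkhead and Scalloped sites stayed past the threshold, with odds ratios of 1.51 for Mef2 (2.04 against flanks) and 1.23 for forkhead (1.65 against flanks). The GAGA factor site then passed as well (3.42% against 1.67%, odds ratio 2.09, Fisher's exact adjusted p = 0.0100), while the Mad site was at 5.88% against 5.66% and TATCGATA at 2.02% against 1.01% (Fisher's exact adjusted p = 0.055). Over the 399 summits more than 2 kb from a TSS, a set chosen after seeing the data, none of the 15 motifs passed, with the Mef2 site at 6.02% against 6.64% and the forkhead site at 25.3% against 23.6% (Fisher's exact adjusted p = 0.773 for each). In the list of replicate 2 alone, TATCGATA was at 1.71% against 0.855% (Fisher's exact adjusted p = 0.306).

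In the search over all 2080 6-mers, 258 were enriched at summits and 340 depleted past an adjusted p of 0.05. The leading sequence was TTAAAA, in 43.9% of summit windows and 24.7% of flanks (Fisher's exact adjusted p = 2.2e-26), and 35 of the enriched 6-mers held only A and T. ACAGTG followed, in 258 summit windows (22.6%) against 8.55% of flanks, an odds ratio of 3.12 (Fisher's exact adjusted p = 1.5e-25). Against peaks matched on GC content, 54 6-mers were enriched and ACAGTG led, with an odds ratio of 3.39 (Fisher's exact adjusted p = 2.1e-28). Over the 399 summits more than 2 kb from a TSS, 10 were enriched and ACAGTG led again, in 23.1% against 7.39% (Fisher's exact adjusted p = 2.6e-10). Enriched 6-mers can overlap, as ACAGTG and CAGTGG do in each of these comparisons. They were not merged, so the counts are not of separate elements.

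**Figure D3:**
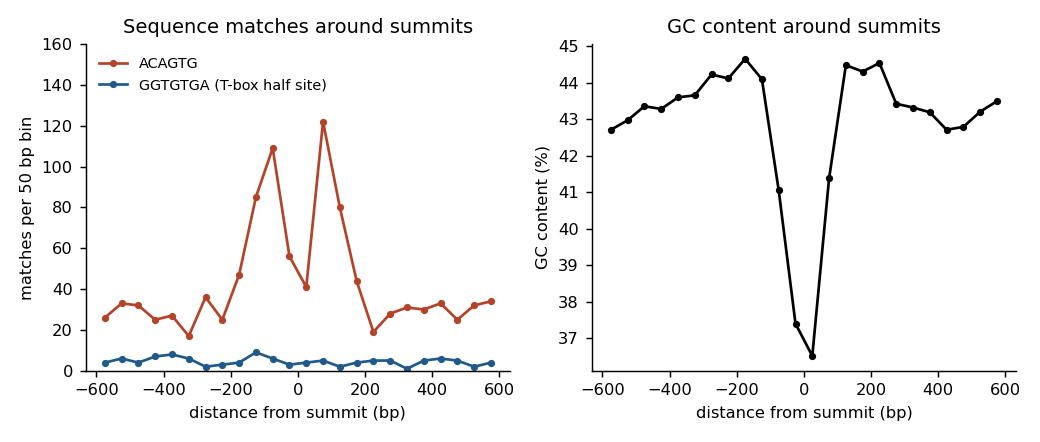
Left, matches to ACAGTG and to the T-box site GGTGTGA on either strand per 50 bp bin of distance from the 1140 summits. Right, GC content in percent in the same bins, which falls to 36.5% beside the summit, while ACAGTG reaches 109 matches from -100 to -50 bp and 122 matches from 50 to 100 bp.

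The fourth question was which developmental genes had a peak. Each peak was given to the gene with the nearest TSS, and each list of genes fixed in advance was compared with 10000 random lists matched on the length of genome nearest to the gene. In all, 969 genes had a peak. Members of a list without a ranked peak were left out, so that 61 of the 88 ribosomal protein genes were counted. The Dorsocross genes themselves (3 of 3 with a peak, 0.302 expected), the other T-box genes (4 of 5, 0.788 expected) and the ribosomal protein genes (12 of 61, 4.50 expected) had more genes with a peak than the random lists, with adjusted two-sided permutation p of 0.0306, 0.0348 and 0.0306. The 3 Dorsocross genes lie together on 3L, from 9005196 to 9045042, and H15 and mid on 2L, from 5404280 to 5467610. Random lists draw genes from across the genome, so the p-values of both T-box lists take neighbouring genes as independent and may be too small. Among the other T-box genes, the peak of highest signal was 335 bp upstream of org-1, in intergenic sequence (FBgn0021767; X, 8455376 to 8455468; signal 203 in the series list, 145 in replicate 1 and 55.9 in replicate 2). The peaks given to mid (signal 86.6), bi (75.4) and H15 (63.3) were 15241 bp, 19146 bp and 15008 bp from a TSS, and byn had none. The ribosomal protein peaks of highest signal were intergenic and upstream of RpS27 (301, at 30 bp), RpL32 (224, at 140 bp), RpL34b (217, at 53 bp) and RpL23A (161, at 109 bp). These list calls changed under many of the alternatives. Without replicate 2 only the housekeeping list passed, and the share for both T-box families fell to 33.3% and 20%. Without replicate 1 no list passed. With the conservative list, the Dorsocross genes were the only list past the threshold, and with a Fisher's exact test against all genes without matching 6 lists passed. The ribosomal protein genes did not pass in that test (12 of 88; Fisher's exact adjusted p = 0.0515). With peaks given to every gene within 5 kb of the gene body, neither T-box family passed (permutation adjusted p of 0.0567 and 0.381). The other T-box genes also lost their call with peaks within 2 kb of a TSS (1 of 5; permutation adjusted p = 1) and against draws of ranked peaks (permutation adjusted p = 0.165).

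The lists for tissues in which the Dorsocross genes are known to act did not pass the threshold against matched random lists. Of the 22 heart and dorsal mesoderm genes, 20 had a ranked peak and 6 of those 20 had a series peak (2.93 expected, permutation adjusted p = 0.305). Among them were zfh1 (signal 136, intron), sli (99.8, intron) and bin (94.2, 1234 bp upstream). The heart list passed in the unmatched Fisher's exact test, with 6 of 22 (Fisher's exact adjusted p = 0.0113), as did the Dpp and EGF receptor lists described next (Fisher's exact adjusted p = 0.00378 for each). Of the amnioserosa and dorsal ectoderm genes, 3 of 16 had one (2.29 expected; permutation adjusted p = 1): ush (98.0), dpp (82.9) and tkv (74.6), each in an intron of its gene. For Dpp signalling the count was 6 of 14 (1.87 expected; permutation adjusted p = 0.0576), with the receptor gene wit (120, intron), the transcription factor gene shn (104, intron), the repressor gene brk (89.9, 811 bp upstream, in an intron of CG1677) and the secreted antagonist gene sog (87.0, intron). With peaks given to genes within 5 kb of the gene body, Dpp signalling passed, with 10 of 17 (3.81 expected; permutation adjusted p = 0.0372). For EGF receptor signalling it was 5 of 12 (1.98 expected; permutation adjusted p = 0.187), led by the ligand gene spi (161, in an intron 173 bp upstream of its nearest TSS), the antagonist gene aos (144, intron), S (91.8) and aop (80.7). Of the 12 housekeeping genes, 7 had a ranked peak and 3 of those 7 had a series peak (0.463 expected, permutation adjusted p = 0.0576): Hsp83 (148), sqh (97.3) and Act5C (92.4). Against draws of ranked peaks, where all 12 were counted, the housekeeping list passed with 3 of 12 (0.231 expected, permutation adjusted p = 0.0240).

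The remaining lists did not pass the threshold against matched random lists, with permutation adjusted p from 0.337 to 1. Wnt signalling had 3 of 17 genes with a peak (sgg 154, Wnt6 92.9, nkd 73.8), the Notch and E(spl) list 2 of 14 (E(spl)m3-HLH 147, E(spl)malpha-BFM 84.7), segmentation and Hox genes 4 of 25 (slp2 134, Antp 98.1, slp1 90.5, Dfd 86.1), and appendage genes 2 of 10 (Dll 115, hth 102). With gene bodies and 5 kb the Notch list passed, with 9 of 16 (2.87 expected, permutation adjusted p = 0.0144). Genes of the E(spl) complex lie close together on 3R, so under that rule 1 peak can count for several of them. Random lists draw genes from across the genome, so this test cannot tell a preference for the list from such shared peaks. Tracheal genes had 2 of 9 (vvl 127, grh 61.7), gut and Malpighian tubule genes 2 of 10 (bowl 151, ct 87.1), epidermal genes 3 of 8 where 1.07 was expected (ovo 109, sn 95.9, grh 61.7; Fisher's exact adjusted p = 0.0431 in the unmatched test) and somatic muscle genes 4 of 16 where 1.87 was expected (sls 100.2, kirre 83.2, sns 65.3, mbc 64.9). Neural genes had 1 of 14, elav (280, in an intron of arg, 265 bp upstream of elav), and haemocyte and fat body genes 0 of 11, where 0.980 was expected.

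**Figure D4:**
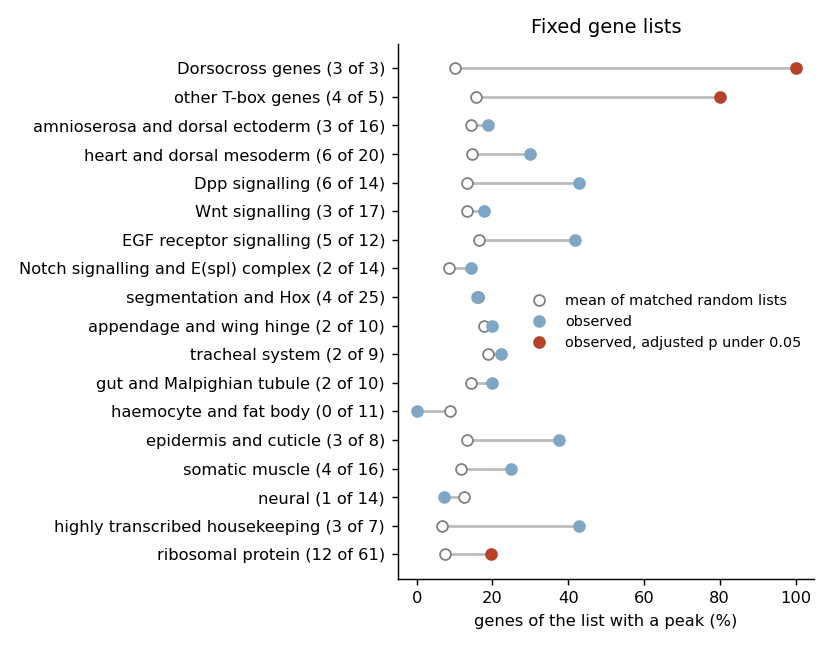
Percent of the counted genes of each fixed list, those with a ranked peak, that had a series peak (filled circles), and the mean of 10000 matched random lists (open circles). Brackets give the number of genes with a series peak and the number of list members counted. Red marks the 3 lists with an adjusted p under 0.05: Dorsocross genes (3 of 3), other T-box genes (4 of 5) and ribosomal protein genes (12 of 61).

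The last question concerned the locus of the tagged gene. Within 50 kb of Doc2 (FBgn0035956), a window of 107 kb on 3L from 8962686 to 9069246, there were 12 series peaks, a number reached or exceeded by few of 13137 windows of that width along the genome (percentile 99.98, mean 0.925). The peak of highest signal lay in intergenic sequence 6659 bp upstream of Doc2 (9025730 to 9026079; signal 210 in the series list, 136 in replicate 1 and 86.9 in replicate 2) and was the only Dorsocross peak in the lists of both replicates. Peaks also lay in coding exons of Doc2 (9018673 to 9019022, signal 103), Doc1 (9043393 to 9043742, 84.6) and Doc3 (9006519 to 9006868, 78.0, with an overlapping second peak of 4.44). Higher than these exon peaks were peaks outside the Dorsocross genes with signals of 146 (summit at 9045467) and 110 (summit at 9057874). The 12 peaks also include a weak one of 5.37 (summit at 8996597) beside one of 98.1. The 152 ranked peaks of the window had a median signal of 36.5, against 23.3 for all ranked peaks (percentile 99.96 among windows). This raised ranked signal, which was uneven over the window, limits what peak counts there can show.

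**Figure D5:**
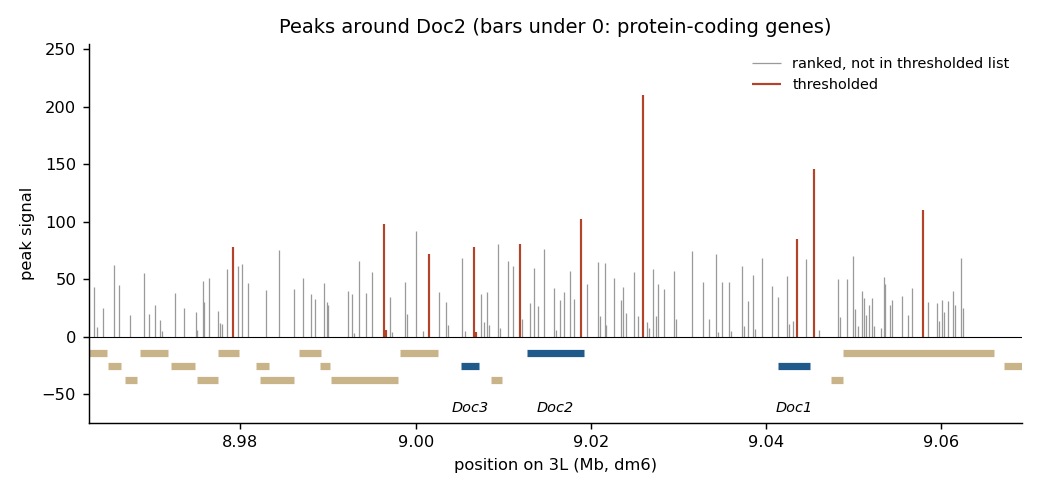
Signal of each peak of the ranked list (grey) and of the thresholded list (red) by position on 3L in Mb, with protein-coding genes as bars under 0 and the 3 Dorsocross genes in blue. The peak between Doc2 and Doc1 reaches 210, and 12 thresholded peaks fall in the 107 kb shown.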

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

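The test of excluded regions below was set before its result was seen; for the Dorsocross locus, the test on neighbouring bins was chosen after the values were seen and the test on other genes before.

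In the series ranked list, 1403 peaks reached the IDR threshold and 173 of them are not in the thresholded list, which drew attention because 2 of them exceed every signal in that list. The highest is 2669, on unplaced sequence, against 1054 for the highest peak in the thresholded list. On the 6 chromosomes analysed there were 74 such peaks, with a median signal of 103, and 28 of them lay on X beyond 22 Mb. If whole regions had been excluded by the authors, the same places should be missing from every list: 1 of the 173 overlapped a peak kept in another thresholded list, which is consistent with exclusion by region. Whether binding occurs there was not tested, and the design has no second group that gives a biological explanation to test.

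A further 90 thresholded peaks lay outside the chromosomes analysed, with a median signal of 96.9 against 105 on the chromosomes. Of these, 4 lay on the assembled Y and 86 on 67 other sequences, among which unplaced pieces of Y were not counted apart.

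The raised signal around Doc2 is the other pattern weighed. With thresholded peaks left out, 6 of the 11 bins of 10 kb around the gene had a median ranked signal above the 95th percentile of 10768 bins (33.7), and 4 of them were neighbours, a run that no other place in the genome equalled. Loci of developmental genes in general did not share this level. The 191 windows around genes of the other developmental lists had a median of 24.0, against 23.6 over all windows of that width. The highest of them was Kr with 34.8. That 0 of 191 reached the 36.5 of the Doc2 window adds little, since few windows anywhere do (percentile 99.96). Extra copies of the locus carried by the transgene would raise signal over neighbouring bins in this way and remain open, since the extent of the transgene and the control library were not analysed here. Binding of Doc2 across its own locus was not tested against this, so the list result for the Dorsocross genes may share the same origin.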

How the results depend on the processing

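Comparisons on peaks over 2 kb from a TSS, on merged overlapping peaks and with the Dorsocross genes removed were chosen after seeing the data; all others were planned. Replicate overlap kept its direction and its side of the threshold under each of 3 alternatives (72.9% to 81.6%), as did the promoter share under each of 8 (30.2% to 58.2%). The T-box site stayed short of the threshold under each of 11 alternatives (0.351% to 3.95%), though it was above its background with GC-matched peaks and with peaks over 2 kb from a TSS. The Spearman correlation of replicate signal moved to 0.260 over all ranked peaks, which include those without repeatable ranks, and Pearson's r was 0.842. Without one replicate, the number of motifs past the threshold was 5 to 6, of enriched 6-mers 203 to 274, and of gene lists 0 to 1, the lists then being shorter. Enriched 6-mers fell from 258 to 54 with GC-matched peaks, a background that also replaced flanks by other peaks, so the cause was not tested, and to 10 over 399 peaks over 2 kb from a TSS, where 0 motifs passed Fisher's exact test (0 also before adjustment). Of 18 gene lists, 3 passed; the count was 1 with the conservative list, 0 with the 570 peaks of highest signal (1 before adjustment), 0 with peaks over 2 kb from a TSS (2 before adjustment) and 6 with the unmatched Fisher test; with gene bodies and 5 kb it was 3, of which only the ribosomal protein genes were among those of the main test, and the cause was not tested. The share of peaks on X passed, without adjustment over settings, at 20.7% for the 570 peaks of highest signal only, cause not tested. The 10 kb window around Doc2 held 5 peaks, being smaller. Reversed directions that involved a call were those of the Mad site (21.8% against 20.3% with 250 bp windows, 5.88% against 5.66% with GC-matched peaks), the GAGA factor site (15.3% against 8.20% with 250 bp windows, 3.42% against 1.67% with GC-matched peaks), the Mef2 site over 2 kb from a TSS (6.02% against 6.64%) and ribosomal protein genes there (0%), the cause not tested. Of 291 values for single motifs and lists, 246 stayed on their side of the threshold, 24 lost the threshold, 15 gained it and 6 reversed with a call on either side. Among the 246, direction was kept by 195 and turned in 51 (15 for motifs, 36 for lists), none of which were past the threshold in either setting. No paired analysis was possible because there was 1 group. Read depth is unknown, so its limits on weak peaks could not be assessed.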

Other observations

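The tests of base composition and promoter sequence, the strand counts and the genes with several peaks were chosen after the values were seen; the tests of repeats, of pairs and of divergent promoters were set before.

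Some genes collected several separate peaks, named here after their values were seen. CHES-1-like, a forkhead box gene, had 6 peaks that did not overlap, over 48.7 kb of nearest sequence, and the kinase gene Raf had 5 over 21.2 kb. The genes chinmo, Tlk, dnc and CG6163 had 4 each, and ph-p was among several with 3 after overlapping peaks were merged, over 9.98 kb.

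Many promoter peaks sat between a pair of divergent genes. Of 503 promoter summits, 182 (36.2%) lay between TSSs on opposite strands that point away from each other, each within 500 bp, against 3.98% of 13261 promoter summits of ranked peaks below the threshold (Fisher's exact p = 1.3e-109). Among summits upstream of the nearest TSS, a comparison added afterwards, the shares were 37.8% and 9.03% (Fisher's exact p = 6.8e-52). The hypothesis that shared promoters are more frequent among these peaks than among ranked peaks below the threshold held in both. Promoters in general were not used as a background, so a preference for shared promoters over other promoters was not tested.

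The sequence ACAGTG flanked the summits in an ordered way. It occurred from 25 to 150 bp of 331 summits (29.0%), and to the left of the summit 171 of 221 matches read ACAGTG on the plus strand (77.4%), while to the right 178 of 228 read CACTGT, so that copies on opposite sides mirror each other (Fisher's exact p = 2.7e-33 for left against right). Both sides carried it at 91 summits, where 39.1 would be expected from independent sides (2.33 times, permutation p = 0.0001, the smallest that can be had). The hypothesis of paired elements around an AT-rich centre predicts such an excess. The permutation gave every summit the same chance of the element, although its share rose with signal. Summits that differ in this chance would also carry it on both sides more often, so the test cannot tell pairing from such differences. It flanked 19.6% of the 285 summits with the lowest signal, 26.0% and 31.9% in the next sets of 285, and 38.6% of those with the highest.

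Technical origins of the ACAGTG pattern were weighed. Base composition alone is argued against by the odds ratio of 3.39 (95% interval 2.76 to 4.16) against peaks matched on GC content, and promoter sequence alone by 3.74 (2.63 to 5.32) at summits over 2 kb from a TSS. Copies of a repeat that is masked in the reference are argued against by the 0.408% of 490 matches (95% Wilson interval 0.112% to 1.48%) that lie in repeat-masked sequence, which covers 17.8% of the bases in these windows. Copies of an element that is not masked could not be seen this way. Recovery of open or factor-rich chromatin by the antibody regardless of Doc2 stays open, because no ChIP from embryos without the tagged protein was used here. The T-box site, which passed the threshold neither against flanks nor against peaks matched on GC content, does not settle it. Apart from the pairing of the elements, no biological explanation was tested, since the design has 1 group.

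GAGAGA and CAGCTG also had their highest counts beside the summit, which were not tested. GAGAGA had 101 matches from -150 to -100 bp and 100 from 150 to 200 bp, against 33 and 28 in the 50 bp to either side of the summit and 22 to 82 per 50 bp from 200 to 600 bp. CAGCTG had 58 from -150 to -100 bp and 63 from 100 to 150 bp, against 22 and 25 in the 50 bp to either side and 21 to 41 per 50 bp from 200 to 600 bp.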
